A study of Mus musculus with 2 samples.

How the data were processed

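DNase-seq was carried out on midbrain tissue of mouse embryos at day 14.5, from pooled males and females, in 2 biological replicates of 1 group. Groups and replicate numbers were taken from the labels. Per the labels, the files are on the mouse assembly mm10. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate had its own list of peaks and its own list of hotspots, so the authors called them per replicate and not on pooled reads.

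The deposited peak lists give intervals of 150 bp, apart from 2 in replicate 1 that are narrower (smallest 85 bp), each with a signal value that is a whole number of at most 150. The p and q columns of these lists hold no values. The values are not scaled to a common depth and crowd towards 150 in replicate 2, where 6.70% of peaks exceed 120 against 0.242% in replicate 1, so they were used to rank or filter peaks within a replicate, and their ratio between replicates only in a test of sequencing depth. In the deposited hotspot lists each region carries a −log10 q value, from the threshold at q = 0.05 to a cap of 100, and a display score that follows it. The score was not used. At the cap stood 134881 hotspots of replicate 1 (21.3%) and 81520 of replicate 2 (36.7%). All peaks lay within hotspots. The total of the peak values was 7975409 over 101.9 Mb in replicate 1 and 16371884 over 39.7 Mb in replicate 2. Neither is a read depth, which is unknown.

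Coordinates are 1-based on mm10. The sequence was GRCm38.p6 and the annotation GENCODE mouse release M21. As a check on the build, 99.9% of 59255 annotated start codons read ATG in the sequence, and no peak ran past the end of its chromosome or held an unknown base. Genes were the 21911 named protein-coding genes on chromosomes 1 to 19, X and Y. The analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.

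Peaks were called shared when they overlapped a peak of the other replicate by at least 1 bp, and shared peaks were described by the replicate 2 interval. The overlap expected by chance came from 100 shuffles of each replicate's peaks within their chromosomes. A peak was near a start when its centre lay within 1000 bp of a protein-coding transcript start, and distal otherwise. A promoter was open when a shared peak overlapped the 1000 bp on either side of any annotated transcript start of the gene. Shares of each list were set against all remaining protein-coding genes by two-sided Fisher's exact tests. Distal peaks were counted in the gene body and 50 kb either side, and the list median was compared with 10000 random lists matched on decile of gene length, in a two-sided permutation test whose smallest p is 2e-04. Midbrain regulators were compared with 5 other lists by 100000 permutations of list membership. Benjamini-Hochberg adjustment covered the 18 lists, or the 5 comparisons, at a threshold of 0.05. A gene stands as the unit in these tests and is not a biological replicate.

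Motifs were counted as exact matches to 28 consensus sequences on either strand, in the 150 bp around the centre of distal peaks and in windows of the same width centred 1000 bp to each side. Intervals of shares are 95% exact binomial (Clopper-Pearson). Motif shares had no test across libraries.

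The 18 gene lists were midbrain and isthmus regulators, dopaminergic neuron genes, other transmitter genes, forebrain regulators, Hox genes, neural progenitor genes, pan-neuronal genes, oligodendrocyte and astrocyte genes, endothelial and pericyte genes, microglia and myeloid genes, erythroid genes, mesenchyme and meninges genes, liver genes, skeletal muscle genes, keratinocyte genes, germline genes, cell cycle genes and housekeeping genes. They held 328 genes of the annotation. Of the 15 erythroid genes 1 was not found under its name, and 6 dopaminergic genes were also midbrain regulators. The gene lists, the motifs, the tests, the rule for naming genes and most alternatives were chosen before the data were examined. The named-gene rule took, for each list, the 3 members with the highest mean percentile rank of their strongest promoter peak over both replicates, then members of the midbrain, forebrain, progenitor and pan-neuronal lists with no promoter peak in either replicate (there were none), then up to 3 members of each list of another tissue, in alphabetical order, with a promoter peak in both replicates. It also took the 10 genes with the most shared distal peaks and the 10 shared peaks with the highest mean percentile rank. Not planned, and added after the first results were seen, were the En1 region, the ranking of nuclear peaks, the splits of peaks by value and by genomic class, the comparisons of the midbrain list with other lists and the CpG-matched test in each replicate alone.

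The programs were tested on simulated data. The overlap step found 40% of 5000 simulated peaks shared where 40% were planted. Of 200 simulated unchanged lists, 4% had p under 0.05 in Fisher's exact test, 2% in the CpG-matched promoter test and 5.5% in the distal permutation test. Of 100 lists with a planted increase, these tests called 78%, 19% and 78% in the right direction, so the CpG-matched promoter test missed most of them. The promoter increase was planted without regard to CpG, so its size against CpG-matched lists was not set. No decrease was simulated. Motif folds planted at 1.5 and 3 came back as 1.48 and 3.05, and all 56 motif copies planted over both strands were found.

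The alternatives tried were a 50% reciprocal overlap or centres within 500 bp in place of 1 bp, the strongest 50% of peaks (25% for motifs) or matched list lengths, hotspots in place of peaks, autosomes alone, promoter windows of 500 bp and 2000 bp, all transcripts or gene starts alone, random lists matched on promoter CpG count, distal windows of 20 kb and 100 kb, no matching on gene length, random windows matched on GC content, motif windows of 100 bp, other correlation measures, and each replicate without the other. Another 6, chosen after seeing the data, were a promoter peak in each replicate whether overlapping or not, shared distal peaks and single-replicate peaks defined by centres within 500 bp, flanking windows kept off peaks, autosomes and X alone for the share near starts, and CpG matching combined with peaks of each replicate alone or in each replicate. Peaks on the mitochondrial chromosome and on unplaced contigs were left out of the gene list, motif, chromosome and single-replicate results. Some genes and a motif that these rules cover are not reported here. Signal tracks and reads were not used here.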

Results

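Open chromatin in the midbrain of mouse embryos at day 14.5 was mapped by DNase-seq, in which the nuclease DNase I cuts accessible DNA and the positions of the cuts are read by sequencing. Active promoters, enhancers and insulators appear as short peaks of cuts. At this age the midbrain holds dividing progenitors along the ventricle and newly born neurons, among them the dopaminergic neurons of the ventral midbrain. The tissue came from pooled male and female embryos of the strain B6NCrl. The samples formed 1 group of 2 biological replicates, listed as separate biosamples under a single donor entry, so the spread between them may be partly technical. No other tissue or age was analysed here, and the comparisons are between the replicates, between gene groups, and between peaks and other genomic sequence.

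Replicate 1 held 710176 peaks covering 101.9 Mb, and replicate 2 held 267958 peaks covering 39.7 Mb. The authors' value of a peak had a median of 6 in replicate 1 and 51 in replicate 2, with a maximum of 150 in both. Wider accessible regions, called hotspots, numbered 633971 in replicate 1 and 222362 in replicate 2. The read depth of the libraries is unknown, so values were used within a replicate, and their ratio between replicates only in the test of depth at the end. Peaks and genes were the units of the tests and are not independent biological replicates, and all intervals cover counting error only.

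Of the replicate 2 peaks, 171429, or 64.0% (95% exact binomial interval 63.8 to 64.2), overlapped a replicate 1 peak. Peaks of the same number and width placed at random overlapped in 7.81% ± 0.0536 (SD over 100 shuffles). In the opposite direction, 24.7% of the replicate 1 peaks overlapped a replicate 2 peak, against 3.10% ± 0.0183 at random. When only the strongest 267958 peaks of replicate 1 were kept, to match the length of the replicate 2 list, the shares were 61.4% for replicate 1 and 60.5% for replicate 2.

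Strong peaks were nearly all found in both replicates and weak peaks were not. Among replicate 1 peaks with values of 5 or less, 1.15% overlapped a replicate 2 peak (exact binomial interval 1.11 to 1.18), whereas the share was 96.8% at values above 40 and up to 50 and 99.5% above 120. In replicate 2 the share was 25.7% at values above 20 and up to 30 and 98.4% above 120. Across the 171429 shared peaks the values of the replicates were ranked alike, with a Spearman coefficient of 0.899. The plot of peak values shows both distributions.

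**Figure D1:**
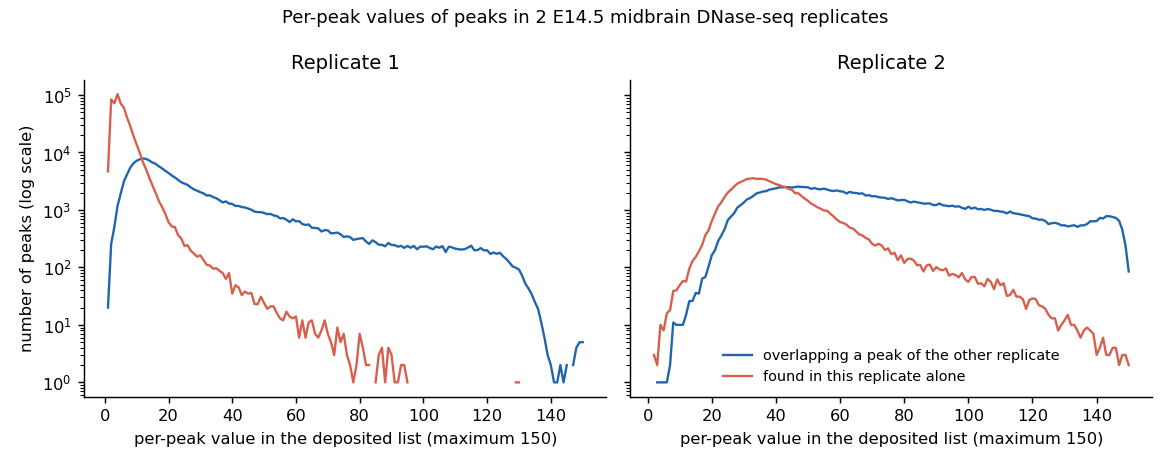
Number of peaks (log axis) at each whole-number value (no unit, maximum 150) in replicate 1 (left) and replicate 2 (right), for peaks that overlap a peak of the other replicate (blue) and peaks found in that replicate alone (red). The peaks found alone tend to lower values, with a median of 5 in replicate 1 and 38 in replicate 2, against 19 and 66 for shared peaks, and both kinds reach 150.

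Of the 10 shared peaks with the highest mean percentile rank, 9 lay on the mitochondrial chromosome, whose DNA carries no nucleosomes. The remaining peak lay at the promoter of Hjurp, which encodes the chaperone of the centromeric histone variant CENP-A. It spanned bases 88277556 to 88277705 of chromosome 1 (mm10) with values of 148 and 150 in replicates 1 and 2. With the mitochondrial peaks set aside, a ranking made after the values were seen, the next peaks lay at the promoters of Fam76a (chromosome 4, 132922696 to 132922845, values 141 and 150), Ints7 (chromosome 1, 191575576 to 191575725, values 139 and 150) and Nfya (chromosome 17, 48409656 to 48409805, values 138 and 150). Ints7 encodes a subunit of the Integrator complex and Nfya a subunit of the transcription factor NF-Y. Of the 100 highest nuclear peaks, 96 lay within 1000 bp of a protein-coding transcript start.

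Shared peaks were concentrated at promoters, and the more so the stronger the peak. A protein-coding transcript start lay within 1000 bp of the centre of 30845 shared peaks, or 18.0% (exact binomial interval 17.8 to 18.2), against 2.60% ± 0.0400 of peaks placed at random (SD over 100 shuffles). The share was 43.8% among the 42857 shared peaks with the highest replicate 2 values and 4.99% among the 42858 with the lowest. Introns held 40% of shared peaks, against 41.9% at random, exons beyond the promoter windows 5.58% against 4.39%, and intergenic sequence 36.4% against 51.1%. All replicate 2 peaks gave a share near starts of 15.3%, and all replicate 1 peaks, which include many weak ones, gave 6.83%.

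Promoters of midbrain transcription factors and signalling genes, of neural progenitor genes and of pan-neuronal genes were open throughout in both replicates, and most promoters of erythroid, liver and germline genes were not. Of 21911 protein-coding genes, 15107 (68.9%) had a shared peak overlapping the 1000 bp on either side of an annotated start. All 30 midbrain and isthmus regulators had one (Fisher's exact test, adjusted p = 0.00049), a call lost against random lists matched on promoter CpG (100% against 96.9%, permutation test, adjusted p = 1). The values given for a gene are those of its strongest promoter peak in replicates 1 and 2, and the genes of a list are ranked by the mean percentile rank of these values over both replicates. Highest in rank in the midbrain list were En2 (chromosome 5, 28165496 to 28165645, values 111 and 141), Pou4f1 (chromosome 14, 104467996 to 104468145, values 94 and 140) and Pax5 (chromosome 4, 44704476 to 44704625, values 92 and 141). En2 and Pax5 encode transcription factors of the midbrain and hindbrain boundary region, and Pou4f1 a POU factor of tectal and red nucleus neurons.

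All 20 neural progenitor genes and all 20 pan-neuronal genes also had a shared promoter peak (Fisher's exact test, adjusted p = 0.00292 for each list). Both calls were lost with CpG matching (permutation tests, adjusted p = 0.839 and 0.182). Among the progenitor genes the highest in rank were Id4 (116 and 147), an inhibitor of bHLH factors, Hes1 (97 and 142), an effector of Notch signalling, and Ptprz1 (92 and 142), a receptor phosphatase of radial glia. Among the pan-neuronal genes they were Tubb3 (123 and 147), which encodes neuronal beta-tubulin, Mapt (107 and 145), which encodes tau, and Elavl3 (104 and 145), which encodes a neuronal RNA-binding protein. The 24 forebrain regulators were open at 23 promoters (adjusted p = 0.0061 in the same exact test, adjusted p = 1 with CpG matching), with high values at Bcl11b (103 and 141) and Lhx2 (102 and 142). Lhx6, a factor of cortical interneurons named after its values were seen, had a promoter peak in replicate 2 alone, with a value of 85.

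Genes of dopaminergic neurons had a shared promoter peak at 13 of 15 members, a share that did not pass Fisher's exact test (adjusted p = 0.204). En1 (94 and 138), Kcnj6 (81 and 138) and Nr4a2 (62 and 133) ranked highest. Th, which encodes the rate-limiting enzyme of dopamine synthesis, and Aldh1a1, a retinaldehyde dehydrogenase of ventral midbrain neurons, had promoter peaks in replicate 2 alone, with values of 42 and 40, and were named after their values were seen. With replicate 2 peaks alone all 15 genes had a promoter peak and the list passed the exact test (adjusted p = 0.0294). It did not pass the permutation test against lists matched on promoter CpG (100% against 87.5%, adjusted p = 0.328). At 100% the list could not have stood higher in that test. Other transmitter genes were open at 14 of 15 promoters (adjusted p = 0.0728 in the exact test), with Gad1 (75 and 119), which encodes a GABA-synthesising enzyme, Slc17a6 (56 and 120), a glutamate transporter gene, and Slc32a1 (54 and 119), a GABA transporter gene, at the top. The exception was Dbh, the noradrenaline synthesis gene, named after its values were seen, which had a promoter peak of value 4 in replicate 1 alone. With gene 5' ends alone, the other transmitter list lay 2.32 percentage points above the remaining genes, against 24.4 with any annotated start.

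Housekeeping genes were open at 20 of 20 promoters and cell cycle genes at 16 of 16 (Fisher's exact test, adjusted p = 0.00292 and 0.00853), and both calls were lost with CpG matching (permutation tests, adjusted p = 1 each). Rpl13a (138 and 148), Eif4a1 (135 and 147) and Eef1a1 (120 and 148), which encode a ribosomal protein and factors of translation, ranked highest among the housekeeping genes, and Ccna2 (129 and 147), Birc5 (119 and 147) and Mcm5 (115 and 147) in the cell cycle list.

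Erythroid, liver, germline and myeloid genes lay below the remaining genes. Shared promoter peaks were found at 4 of 14 erythroid genes (Fisher's exact test, adjusted p = 0.00572), 4 of 15 liver genes (adjusted p = 0.00292), 3 of 15 germline genes (adjusted p = 0.00119) and 5 of 15 microglia and myeloid genes (adjusted p = 0.0141). With CpG matching the erythroid, liver and myeloid calls were lost (permutation tests, adjusted p = 0.82, 1 and 0.839). The open erythroid promoters included those of Tfrc (118 and 144), the transferrin receptor gene, Tal1 (61 and 132) and Epor (27 and 101), while the alpha- and beta-globin genes, named after their values were seen, had no promoter peak in either replicate. The open liver promoters were those of Apob (62 and 110), Afp (48 and 100), Trf (24 and 68) and, named after its values were seen, Ttr (13 and 51), which is also a choroid plexus gene. The Afp peak lay 10172 bp from the nearest protein-coding transcript start, and counted through another annotated start of the gene. Gdf9 (118 and 140), Dazl (96 and 141) and Tdrd1 (16 and 70) were the open germline promoters, and those of the myeloid list included Irf8 (89 and 139), P2ry12 (23 and 69), C1qb (21 and 60) and C1qa (18 and 49). Klf1 of the erythroid list had a promoter peak in each replicate (10 and 53), but these peaks did not overlap. The myeloid call ended with replicate 1 peaks alone, where 8 of the 15 genes had a promoter peak (adjusted p = 0.104 in the exact test), with windows of 2000 bp (adjusted p = 0.0747) and with hotspots (adjusted p = 0.12).

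Glial, vascular, meningeal, muscle and epidermal lists were not set apart from the remaining genes by the exact test. Oligodendrocyte and astrocyte genes were open at 10 of 15 promoters (exact test, adjusted p = 0.788), with Gfap (72 and 124), Pdgfra (69 and 131) and Mbp (59 and 126) at the top. Endothelial and pericyte genes were open at 8 of 15 (exact test, adjusted p = 0.294), including Esam (50 and 107), Kdr (38 and 114), Erg (37 and 103), Cldn5 (23 and 65) and Abcc9 (14 and 63). Mesenchyme and meninges genes were open at 12 of 15 (exact test, adjusted p = 0.444), including Cyp1b1 (86 and 132), Col1a1 (83 and 129), Fn1 (65 and 132) and Col1a2 (20 and 57), and Col3a1 had a peak in each replicate (11 and 28) without overlap. Skeletal muscle genes were open at 7 of 15 (exact test, adjusted p = 0.115), including Mylpf (115 and 138), Ckm (63 and 108), Myod1 (39 and 105), Des (19 and 69) and Myh8 (14 and 77). Keratinocyte genes were open at 7 of 15 (exact test, adjusted p = 0.115), including Krt10 (102 and 139), Krt1 (53 and 118), Perp (39 and 109), Grhl3 (25 and 110) and Dsc3 (14 and 44), and Dsg3 had a peak in each replicate (9 and 28) without overlap. The peaks of Gfap, Ckm and Krt1 lay 3811, 1487 and 4703 bp from the nearest protein-coding transcript start, and counted through other annotated starts of these genes. The Krt10 peak (99386016 to 99386165 on chromosome 11) lay inside the gene, away from its 5' end at 99389364. It too counted through another annotated start. The nearest protein-coding transcript start, 6 bp away, need not be that of Krt10.

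Hox genes, which pattern the hindbrain, spinal cord and trunk, had a shared promoter peak at 18 of 39 members (Fisher's exact test, adjusted p = 0.0061). Hoxa7 (82 and 123), Hoxb5 (60 and 115) and Hoxa10 (51 and 123) ranked highest. The call was lost in either replicate alone, where 29 and 28 of the 39 genes had a promoter peak (adjusted p = 0.852 and 1 in the exact test), with windows of 2000 bp (adjusted p = 0.296) and with a promoter peak in each replicate, overlapping or not, a setting chosen after seeing the data (adjusted p = 0.202). Against random lists matched on the number of CpG dinucleotides in the promoter, however, the Hox list lay lower by a wide margin, with 46.2% against 96.4%, and it did so in replicate 1 (74.4% against 97.3%) and in replicate 2 (71.8% against 97.8%) alone (permutation p = 2e-04 in each, the smallest that 10000 random lists can give). The permutation took genes as independent, but Hox genes lie in clusters and some share a promoter peak. With the same matching the germline list remained lower (20% against 73.5%, p = 2e-04 in the permutation test), with 46.7% against 79.6% in replicate 1 alone and 26.7% against 78.3% in replicate 2 alone (permutation tests, adjusted p = 0.0108 and 0.0018). Every other call made with shared peaks was lost, and 0 lists lay above the matched lists. With the setting of a peak in each replicate, the mesenchyme list lay above its matched lists (93.3% against 73.5%, adjusted p = 0.0492 in the permutation test). Pan-neuronal genes came nearest, with 100% against 87.8% (permutation p = 0.0304, adjusted p = 0.182). A list at 100% cannot pass when matched lists average near 97%, as for the midbrain, cell cycle and housekeeping lists.

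**Figure D2:**
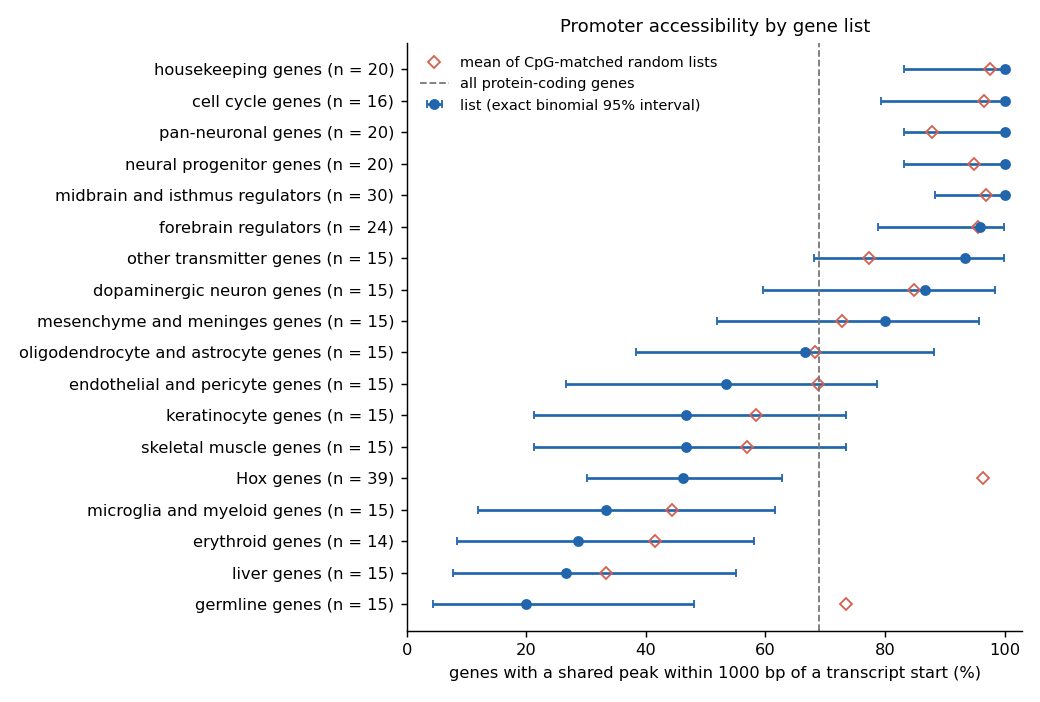
Share of the genes of each list with a shared peak within 1000 bp of a transcript start (blue points, bars are exact binomial 95% intervals, n genes per list), beside the mean of 10000 random lists matched on promoter CpG count (red diamonds) and the share of all protein-coding genes (dashed line, 68.9%). Midbrain, progenitor, pan-neuronal, cell cycle and housekeeping lists reach 100%, and the Hox (46.2%) and germline (20%) lists lie far to the left of their matched lists.

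Away from promoters, the genes of the midbrain, forebrain, progenitor and pan-neuronal lists were surrounded by more open sites than other genes of like length. The random lists here were not matched on promoter CpG, so whether the excess holds against other CpG-rich genes was not tested. Counting shared peaks over 1000 bp from any protein-coding start, within the gene body and 50 kb either side, the 30 midbrain and isthmus regulators had a median of 25.5 peaks, against 6.5 in length-matched random lists (permutation test, adjusted p = 0.0012). Progenitor genes had a median of 19.5 against 6 and forebrain regulators 16.5 against 6 (permutation tests, adjusted p = 0.0012 each), and pan-neuronal genes had 22.5 against 11 (permutation test, adjusted p = 0.00288). Within the midbrain list Pax5 had 40 such peaks, En2 37 and Pou4f1 20, and Meis2, named after its values were seen, had the most with 80. Among the other lists Lhx2 and Bcl11b had 29 each, Id4 19, Hes1 16, Ptprz1 13, Mapt 22, Tubb3 12 and Elavl3 10.

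Hox genes (10 against 5, permutation test, adjusted p = 0.0027), cell cycle genes (11.5 against 5.5, adjusted p = 0.0072) and oligodendrocyte and astrocyte genes (13 against 7, adjusted p = 0.0216) also passed. The Hox genes lie in clusters and share their windows, and so do some neighbours in other lists, such as Dlx1 and Dlx2. The calls for the Hox, cell cycle and glial lists ended without matching on gene length. With windows of 20 kb the calls for the pan-neuronal, cell cycle and glial lists ended, the glial call also ended in either replicate alone, and that for the cell cycle list in replicate 1 alone. The remaining 11 lists did not pass: housekeeping genes had 9 against 5.5 (permutation test, adjusted p = 0.0657), dopaminergic genes 11 against 9, other transmitter genes 10 against 7, myeloid genes 10 against 6, muscle genes 9 against 5, mesenchyme genes 9 against 7, endothelial genes 8 against 9, germline genes 7 against 6, erythroid genes 6 against 5.5, liver genes 5 against 6 and keratinocyte genes 5 against 6.

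In a comparison added after the list medians were seen, midbrain regulators had 15.5 more distal peaks at the median than Hox genes (permutation test, adjusted p = 1e-04) and 16.5 more than housekeeping genes (permutation test, adjusted p = 0.00202). The difference from forebrain regulators, 9 peaks, did not pass the permutation test (p = 0.174, adjusted p = 0.218), and neither did those from progenitor genes (6 peaks, adjusted p = 0.218) or pan-neuronal genes (3 peaks, adjusted p = 0.534). These permutations were not matched on gene length. They also took genes as independent units, which the Hox genes, sharing their windows, are not. Nor are some neighbours in other lists, such as Tfap2b and Tfap2d, Dlx1 and Dlx2, or Nefl and Nefm.

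**Figure D3:**
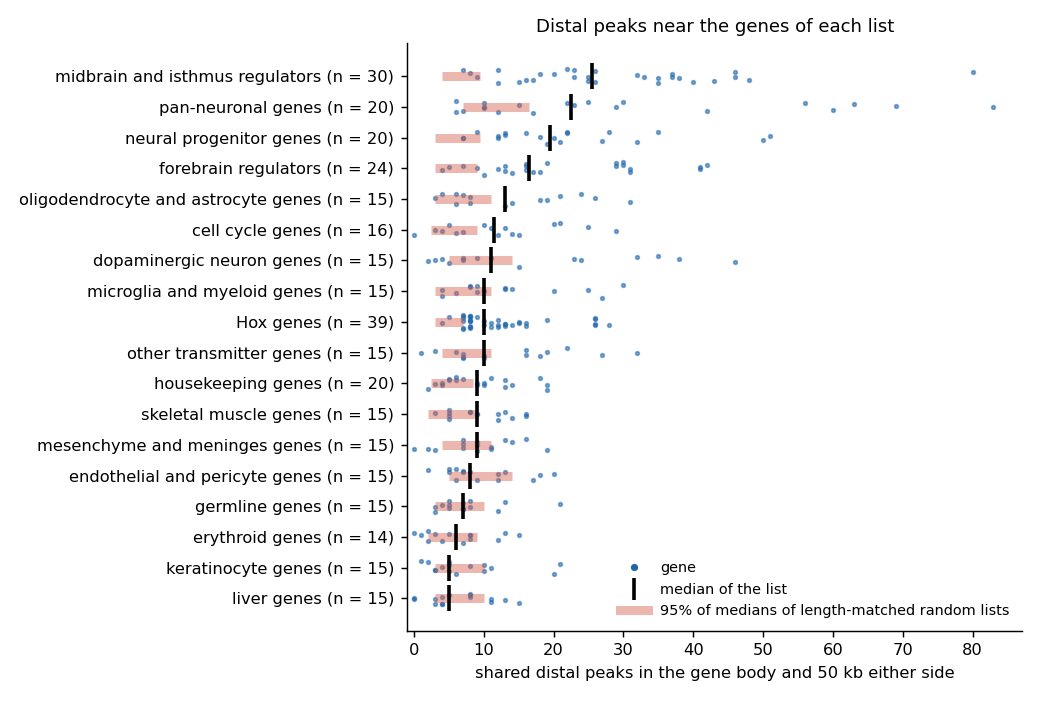
Number of shared distal peaks in the gene body and 50 kb either side for each gene (blue points) of the 18 lists, with the list median (black bar) and the range holding 95% of the medians of 10000 length-matched random lists (red band). The medians of the midbrain (25.5), pan-neuronal (22.5), progenitor (19.5) and forebrain (16.5) lists lie to the right of their bands.

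The protein-coding genes with the most shared distal peaks, counted without regard to gene length, spanned from 353 kb to 4435 kb. Gm20388, annotated over 4435 kb of chromosome 8, had 555, and Fgfr2, a receptor of fibroblast growth factors annotated over 2961 kb, had 308. Then came Auts2 (172), Zfhx3 (170), Rbfox1 (148), which encodes a neuronal splicing factor, Dab1 (146), the adaptor of Reelin signalling, Tenm2 (145), a teneurin adhesion gene, Camta1 (139), Gse1 (137) and Nrxn3 (135), which encodes a synaptic neurexin. A count covers the whole annotated span, so its peaks need not belong to the named gene. Gse1 (120228456 to 120581390) lies within the span of Gm20388 (119910841 to 124345722), so its peaks were counted for both.

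The En1 gene, a homeobox gene needed for the midbrain and for dopaminergic neurons, lies on chromosome 1 at 120602418 to 120607992 on the plus strand. Its window held 38 shared peaks, 35 of them beyond promoters. The strongest, at 120602176 to 120602325, covered sequence just upstream of the start (values 94 and 138). Among the distal peaks, the highest replicate 2 value, 115, was reached by an intergenic peak upstream at 120586596 to 120586745 (59 in replicate 1) and by one downstream at 120643956 to 120644105 (64 in replicate 1), in an intron of the lincRNA gene 2610027F03Rik (120621740 to 120690403, plus strand). Peaks found in 1 replicate alone numbered 29 in replicate 1 and 20 in replicate 2.

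**Figure D4:**
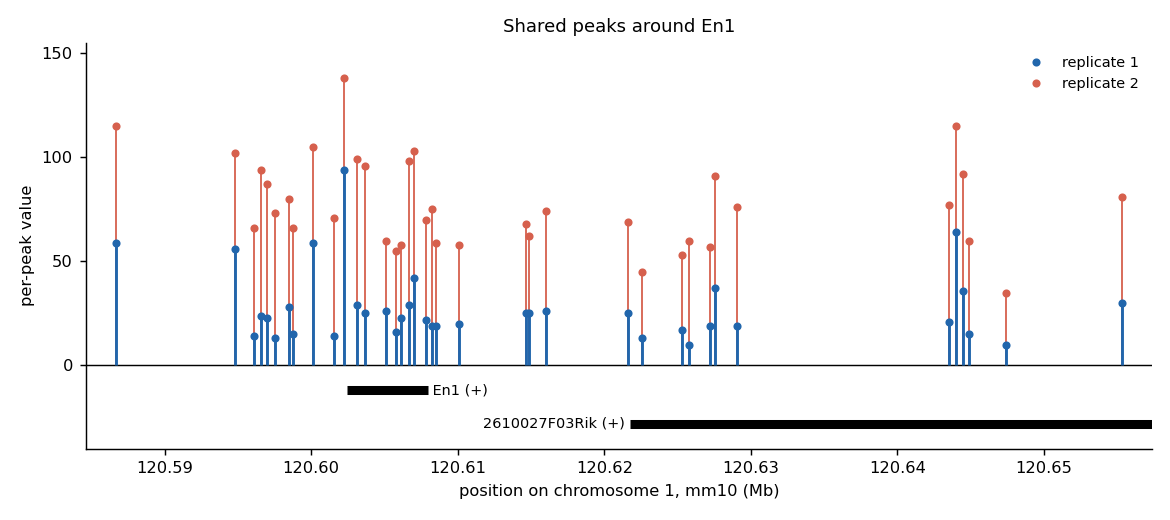
Shared peaks in the window of En1 on chromosome 1 (position in Mb, mm10), with the value of each peak (no unit, maximum 150) in replicate 1 (blue) and replicate 2 (red) as vertical lines, and the annotated genes as black bars. The promoter peak is the highest in both replicates, at 94 and 138, and distal peaks of 115 in replicate 2 stand on either side of the gene.

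Recognition sequences of insulator, ciliary and neurodevelopmental factors were enriched in the distal sites. Of 140378 shared distal peaks, 4.37% (95% exact binomial interval 4.27 to 4.48) held the CTCF motif, CCASYAGRKGGC, which marks insulators, against 0.123% of windows 1000 bp to either side, a fold of 35.5. The NFI motif, TTGGCNNNNNGCCAA, bound by nuclear factor I proteins of glial and late neurogenic progenitors, stood in 0.208% of peaks (0.185 to 0.233), a fold of 27.8. The RFX motif, GTTRCCNNGGYAAC, bound by regulators of ciliary genes, stood in 0.345% (0.315 to 0.378), a fold of 22.6. Others were the EBF motif, TCCCNNGGGA, of the early B-cell factors of differentiating neurons (3.69-fold), NRF1 (3.47-fold), the CRE (2.98-fold), the POU octamer (2.13-fold), SP/KLF (1.73-fold) and TCF/LEF of Wnt signalling (1.70-fold).

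Against random windows matched on GC content the folds were 71.2 for CTCF, 96.7 for RFX, 36.4 for NFI and 7.41 for NRF1. Against flanks kept off peaks, a control chosen after seeing the data, they were 122, 84.7, 45.9 and 4.81, so the order of NFI and RFX depended on the control. In the strongest 25% of shared peaks CTCF stood at 73.8, RFX at 45.6, the CRE at 4.56, SP/KLF at 2.61 and EBF at 2.03.

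In all, 21 of the 28 motifs stood in a larger share of peaks than of flanks, with intervals apart, and 2 in a smaller share. Among frequent short motifs of neural factors Otx stood at 1.23-fold against flanks and 1.28-fold against the GC-matched windows, the Neurog/Neurod E-box at 1.17-fold and 1.05-fold, and Sox at 1.15-fold and 1.29-fold. The TAATTA homeodomain core depended on the control, with 1.20-fold against flanks and 2.73-fold against GC-matched windows. The GATA motif (0.826-fold) and the FOX motif (0.937-fold) were the 2 less frequent ones, and both turned more frequent, at 1.16-fold and 1.27-fold, against random windows matched on GC content, so no direction is given for them. Shared distal peaks held 49.4% GC and their flanks 44.6%. Over all distal replicate 1 peaks the folds were lower than over all distal replicate 2 peaks for CTCF (11.2 against 25.3), NFI (5.95 against 34.1), RFX (7.04 against 17.0) and EBF (1.86 against 5.0), and the SP/KLF motif lay at 0.965 in replicate 1.

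**Figure D5:**
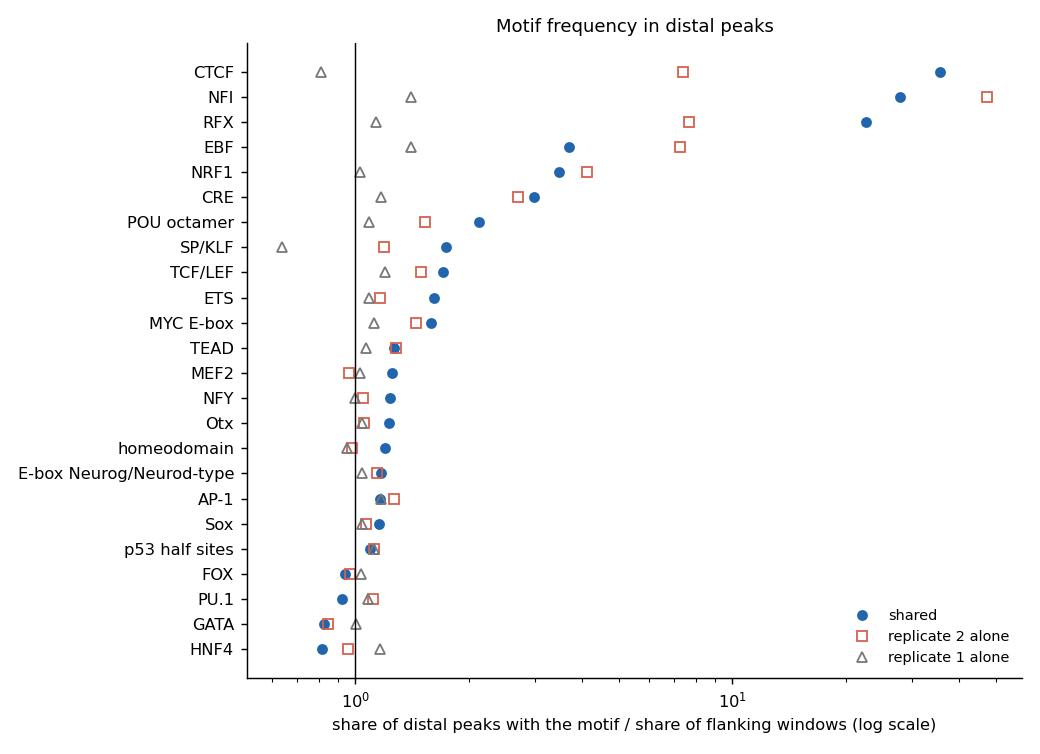
Share of distal peaks with a motif divided by the share of flanking windows 1000 bp away (log axis, 1 marks equal shares), for shared peaks (blue points), peaks found in replicate 2 alone (red squares) and peaks found in replicate 1 alone (grey triangles). CTCF stands at 35.5 in shared peaks, 7.40 in replicate 2 alone and 0.812 in replicate 1 alone.

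The X chromosome carried fewer called peaks per base than any autosome. The embryos were pooled males and females and the counts were not adjusted for the number of X copies. Fewer peaks therefore need not mean fewer open sites. Its density was 121 peaks per Mb in replicate 1 and 41.4 in replicate 2, or 42.1% and 38.6% of the autosome median. The autosomes ranged from 247 to 320 peaks per Mb in replicate 1 and from 94.2 to 141 in replicate 2, with chromosome 11 the densest in both.

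Sites found in a single replicate differed in kind between the libraries. The 534440 nuclear peaks of replicate 1 alone had a median value of 5 against 19 for its shared peaks, lay near a protein-coding start in 3.24% against 17.8%, and held the CTCF motif in 0.0630% of distal peaks against 4.30%, no more often than their flanks (0.812-fold). These flanks were not kept off other peaks. Among the strongest 50% of each list the CTCF share in replicate 1 was 0.257% alone and 6.27% shared. In that setting a peak was alone if it overlapped none of the strongest 50% of the other list. The 96492 nuclear peaks of replicate 2 alone had a median value of 38 against 66, lay near a start in 10.5% against 18.0%, and held CTCF motifs in 0.849% against 4.37%, 7.40 times the share in their flanks. The EBF motif went the other way: it stood in 2.28% (exact binomial interval 2.18 to 2.38) of the distal peaks of replicate 2 alone and in 1.23% of shared ones (1.18 to 1.29). NFI did so too, with 0.275% (0.241 to 0.312) against 0.208% (0.185 to 0.233). Among the strongest 50% of each list the NFI shares turned, with 0.175% alone and 0.187% shared, and the share of replicate 2 peaks near a start was 24.0% alone and 23.7% shared. These shares come from 1 library each and have no replicate check.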

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

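In this part the repeat of the depth test without its highest bin and the repeat of the tissue test without 1 list, the odds ratios in strata of equal value and the tests on the NFI motif were chosen only after the results were seen. The study has a single group, so biological explanations were examined only by comparing gene lists within it, and none was settled.

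Peaks outside the main measurement were found in both libraries, with no control sample to set them against. The mitochondrial chromosome held 30 peaks in replicate 1 and 31 in replicate 2. Chromosome Y held 519 peaks in replicate 1, with a median value of 2, and 56 in replicate 2, with a median value of 44.5. Unplaced contigs held 627 peaks in replicate 1 and 171 in replicate 2.

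Replicate 1 had 2.65 times as many peaks as replicate 2, at lower values. The peaks it had alone may be largely background calls, but the test cannot decide this. Their distal members held the CTCF motif 0.812 times as often as their flanks, a share that true insulator sites would raise. That value met the bound set beforehand for background, but these flanks were not kept off other peaks. For shared peaks, keeping flanks off peaks raised the CTCF fold from 35.5 to 122. That control was not run for peaks of replicate 1 alone. The EBF motif stood at 1.40 times the flanks, but this fold was not matched on GC content. It does not show whether some of these peaks are open sites. A difference in sequencing depth alone cannot be told apart from other differences between the libraries, since read depths are unknown. On a scale that allows for the ceiling of 150, the ratio of replicate 2 to replicate 1 values was 1.59 times larger in the lowest than in the highest bin of values, past the bound of 1.5 set beforehand for a cause other than depth. That bound was not relied on, because the ratio was 1.40 without the highest bin, where the median replicate 2 value of 146 is close to the ceiling.

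Distal peaks found in replicate 2 alone held the EBF motif in 2.28% of cases, against 1.23% of shared peaks. The odds ratio for EBF was 1.86 without strata. By the Mantel-Haenszel method it was 1.45 (95% interval 1.34 to 1.56) in 5 strata of the replicate 2 value. In strata of equal value it was 1.42 (1.32 to 1.53), and in peaks free of repeats, in 5 strata, 1.42 (1.28 to 1.57). Lower values or repeat sequence as the whole cause needed 1.1 at most, and evidence against them needed over 1.5, both set beforehand. The odds ratios in strata fell between these bounds, so by that rule neither explanation was decided. Their intervals exclude 1.1, which argues against either as the whole cause, but this reading was chosen after the values were seen. Lower values took up a part of the excess. For NFI the odds ratios in 5 strata, 1.11 (0.906 to 1.35) and, free of repeats, 1.19 (0.902 to 1.57), include both 1 and the 1.32 without strata, so lower values and repeats cannot be told apart from other causes there. More non-neural cells in replicate 2 may contribute. The share of replicate 2 peaks that replicate 1 lacked was 40.8% around 59 endothelial, myeloid, erythroid and mesenchyme genes. Around 70 midbrain, progenitor and pan-neuronal genes it was 33.4%, so the former lay 7.31 percentage points higher (permutation p = 0.0164). Without the mesenchyme list the difference was 4.23 points, under the bound of 5. The permutation took genes as independent, but C1qa, C1qb and C1qc, like the globin genes, lie in clusters. This explanation too cannot be told apart from others. By list the share was 49.8% for mesenchyme, 42.1% for endothelial, 38.0% for erythroid and 32.9% for myeloid genes, while the dopaminergic and forebrain lists, outside the comparison, had 39.4% and 38.7%, with 0 of the non-neural genes in another list, expression not measured, a promoter peak at Col1a1 in both replicates and none at the globin genes.

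Hox genes had a shared promoter peak less often than other genes of like CpG content. The difference was −22.8 percentage points from all remaining genes and −50.2 from CpG-matched lists, but with the peaks of replicate 1 or 2 alone the first was −1.46 or −0.649, so that it was lost, and the second −23.0 or −26.0. Cells from the neighbouring hindbrain cannot be told apart from midbrain cells as the source of the open Hox promoters: genes of paralog groups 1 to 4, the ones used in the hindbrain, were open in 6 of 12 cases and those of groups 9 to 13 in 8 of 16 (Fisher's exact test, p = 1). The equal shares met the bound set beforehand against this explanation, but 12 and 16 genes are too few to exclude a difference.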

How the results depend on the processing

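Chosen only after seeing the data were the tests with a promoter peak in each replicate, with centres within 500 bp for distal and single-replicate peaks, with flanks off peaks, on autosomes and X, and with CpG matching of peaks in each replicate. The cause of each shift below was not tested unless the setting itself shows it, and read depth, which is unknown, limits every comparison of values. No paired analysis was possible because there is 1 group. Every setting could be run.

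Keeping the strongest 133979 peaks of each list fixed the counts of both replicates by construction. Replicate 1 and replicate 2 peaks were shared in 21.1% and 55.5% of cases with a 50% reciprocal overlap, 32.4% and 76.9% with centres within 500 bp, 61.4% and 60.5% at matched list lengths, 32.5% and 86.3% in the strongest 50% of each list and 26.7% and 66.0% for hotspots, and on autosomes replicate 1 gave 24.8%. The coefficient across shared peaks was 0.912 with reciprocal overlap, 0.892 in the strongest 50%, 0.885 without the strongest 1% and 0.889 as Pearson on log2 values. Near a start lay 13.2% of shared peaks at 500 bp, 22.3% at 2000 bp, 23.7% with all transcripts, 29.3% of the strongest 50%, and 6.83% to 15.3% without one replicate. X density was 28.7% and 29.6% of the autosome median in the strongest 50% of replicates 1 and 2.

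Matched on promoter CpG, 0 lists lay above and 2 below the random lists, and the calls ended for the midbrain (3.08 percentage points), forebrain (0.218), progenitor (5.04), pan-neuronal (12.2), cell cycle (3.38), housekeeping (2.49), myeloid (−11.0), erythroid (−12.9) and liver (−6.64) lists. At 2000 bp 3 lists lay below, the Hox (−9.71) and myeloid (−24.6) calls ended and the other transmitter list passed (28.8). The muscle list passed at 500 bp (−33.9), the keratinocyte list with gene 5' ends (−31.0) and in the strongest 50% (−38.3), the endothelial list in the strongest 50% (−31.6), and the myeloid call ended with hotspots (−22.9). With a promoter peak in each replicate, overlapping or not, the Hox call ended (−10.9), and with CpG matching as well the mesenchyme list passed (19.8). Without one replicate, 3 to 4 lists lay below, and the differences ranged from −1.46 to −0.649 for Hox, from −39.1 to −22.5 for myeloid and from 10.9 to 27.6 for dopaminergic genes.

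Of the distal medians minus those of matched lists, without matching on gene length 4 lists passed, and the calls for the Hox (3 peaks), glial (6) and cell cycle (5) lists ended. With 20 kb windows the pan-neuronal (4.5), glial (2) and cell cycle (3) calls ended, and the other transmitter (6) and myeloid (4) lists passed. With 100 kb windows the other transmitter (8), myeloid (8) and muscle (8) lists passed. In the strongest 50% the cell cycle call ended (3) and the muscle list passed (3). With centres within 500 bp the housekeeping list passed (5). Without one replicate the differences ranged from 6 to 20 for glial and from 9.5 to 10.5 for cell cycle genes. A list stayed on its side of the threshold in 109 distal and 148 promoter comparisons.

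Motif directions turned, on the log2 scale, for GATA (0.22), NFY (−0.00339) and FOX (0.35) against GC-matched windows, and for AP-1 (−0.12) and p53 (−0.12) in the strongest 25%. Without one replicate SP/KLF ranged from −0.0521 to 0.61 and FOX from −0.0742 to 0.0308. Without replicate 2, PU.1 (0.06) and HNF4 (0.11), which had no direction in shared peaks, turned in sign as well. With these, 101 folds moved without a called direction turning and 42 stayed within their interval, and the count of more frequent motifs stayed between 16 and 22. For peaks of replicate 1 alone and replicate 2 alone, reciprocal overlap put 3.72% and 11.2% near a start and EBF at 2.12% in replicate 2. In the strongest 50% the medians were 8 and 60 and the shares near a start 5.95% and 24.0%. There CTCF stood at 0.257% and 1.26%, EBF at 0.640% and 1.63% and NFI at 0.0632% and 0.175%. With centres within 500 bp, 1.96% and 6.91% lay near a start, and in replicate 2 the median was 36, EBF 2.58% and NFI 0.344%.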

Other observations

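The gene families in this part were chosen only after the list results were seen, and none of their values was tested. Shared promoter peaks were found at 42 of 1134 olfactory receptor genes (3.70%, 95% exact binomial interval 2.68 to 4.97), 6 of 328 vomeronasal receptor genes (1.83%), 4 of 57 keratin-associated protein genes and 2 of 42 beta-defensin genes. The median number of CpG dinucleotides in their promoter windows was 10, 8, 16 and 12.

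All 78 mitochondrial ribosomal protein genes and 77 of 80 cytosolic ones had a shared promoter peak, as did 344 of 394 Zfp zinc finger genes and 56 of 67 replication-dependent histone genes. Clustered protocadherins, whose isoforms give neurons distinct surfaces, were open at 52 of 56 promoters, voltage-gated potassium channel genes at 29 of 30, GABA-A receptor genes at 13 of 15 and ionotropic glutamate receptor genes at 19 of 19. All 19 Sox genes and 18 of 19 Wnt genes were open. The promoters of these families held more CpG dinucleotides, with medians from 48.5 in protocadherins to 124 in Sox genes, and the families were not matched on CpG content. Among these families distal peaks, counted without regard to gene length, were most numerous around the glutamate receptor genes, with a median of 21 per gene, against 17 for Sox, 16 for Wnt, 7 for cytosolic ribosomal and 4 for Zfp genes.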
